A study of Mus musculus with 12 samples.

How the data were processed

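Livers of male mice were profiled on single-colour Affymetrix expression arrays, with 1 array per mouse. Per the labels, wild-type and Lats2-CKO mice were 8 weeks old when they were put on a chow without cholesterol or on a high-cholesterol (Paigen) diet with 1.25% cholesterol, and the diets lasted 9 weeks. The labels also call the mutant line a Lats2 knockout, and they do not say which part of the gene was removed or in which cells. Total RNA was extracted with a spin-column kit and 250 ng were turned into labelled cDNA with a whole-transcript kit, per the labels' protocols. The labels number 3 biological replicates in each of 4 groups, which gave 12 arrays.

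The values used were those the authors deposited, as log2 expression per probe set after RMA (background correction, quantile normalisation and summarisation of probes) in Partek 6.6, per the submitters' processing notes. The scale was taken as log2 from the range of the values, which ran from 1.94 to 14.2 over the 12 arrays, and RMA gives log2 values without centring of genes. Version and settings of RMA, the genome build behind the probe sets and any filter on probe sets were not given in the sources used here. Scanner files were not used here, so the background of single probes could not be looked at, and the number of arrays limits the precision of every value. The median over all probe sets was 3.49, 3.48 and 3.427 on the 3 wild-type normal-diet arrays, 3.48, 3.49 and 3.428 on the Lats2-CKO normal-diet arrays, 3.48, 3.423 and 3.429 on the wild-type high-cholesterol arrays, and 3.48, 3.434 and 3.427 on the Lats2-CKO high-cholesterol arrays.

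Probe sets were named through the platform's annotation, with symbols updated by gene identifier against a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names only. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Symbols of 23328 probe sets were taken through the identifier and 193 were kept as the platform table gave them. Probe sets with several symbols or none were left out of the gene tests. For the 1082 genes with more than 1 probe set, the one with the highest mean over all arrays stood for the gene, which left 22180 genes.

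Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the log2 values, in 1 fit over all 12 arrays with 4 group means, so that the groups shared an estimate of the spread. The contrasts were diet within each genotype, genotype within each diet, genotype averaged over both diets, and the interaction of genotype and diet. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Errors of changes are standard errors from this fit, and errors of group levels are SD over 3 arrays.

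For pathways and cell types, 42 gene lists with 835 entries were written down, of which 757 were measured. Each was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 42 lists, and again with an estimated correlation and with fry. Camera asks whether a list's genes moved more than the other genes did, while fry asks whether the list's genes moved on balance in 1 direction. Beside the number of members past the threshold over all genes, the number adjusted over the list alone is given. No list was chosen on these arrays, and the comparisons, tests, lists, alternatives and rule for named genes were all fixed before the data were examined, apart from those said to be added later.

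Genes were named by rule. In each comparison these were the 5 largest rises and 5 largest falls among genes past the threshold whose groups did not overlap. Where fewer passed, those with the smallest unadjusted p and a change of at least 1.5-fold filled the 5 places. From each of the 6 lists with the smallest camera p, up to 3 members past the threshold or else the 1 with the smallest p were named. Predicted and clone-named genes were left out of the first part. A further 17 genes of the Hippo, sterol, p53 and fibrosis pathways were always considered, and 14 of them were measured by a probe set of 1 gene. The others are not analysed here. Other genes are named only with the statement that they were chosen after their values were seen.

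The alternatives fixed in advance were a fit on only the groups compared, the replicate number as a block, a trended and robust prior, no moderation of the variance, array weights, dim genes left out (below the 30th percentile, a value of 3.05), the mean of a gene's probe sets, every probe set, quantile normalisation, median centring, both other list tests, and each array left out in turn. After the data were seen, 2 sets of arrays were noticed at the widest gap between array medians. A block for these sets, alone and together with the loss of wild-type normal-diet array 3, was then added. The gene fit and camera at the preset correlation were first tested on simulated data built from the real genes' means and spreads, with 200 changed genes per comparison. Comparisons of 3 arrays with 3 recovered 25.4% to 49.3% of 1.5-fold changes, 65.7% to 79.1% of 2-fold changes and 95.5% to 98.5% of 4-fold changes. Genotype over both diets recovered 58.2%, 89.6% and 100% of these and the interaction 11.9%, 59.7% and 89.4%. There were 4 to 14 false calls per comparison. A list shifted by -0.5 was called in all 6 comparisons, with 0 other lists called. The simulated noise was independent between genes, so this does not show how often camera calls lists falsely where genes are correlated. The changed genes were drawn at random from all genes, so the recovered shares need not hold for genes with a wider spread between arrays.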

Results

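Liver expression was measured on 12 arrays, 3 from each combination of genotype (wild type or Lats2-CKO) and diet (chow without cholesterol or a Paigen-type diet with 1.25% cholesterol for 9 weeks). Lats2 encodes a kinase of the Hippo pathway, and the design asked how its loss and the diet each changed the liver and whether they acted together. No 2 arrays held identical values, and correlations between arrays over all genes ran from 0.967 to 0.995. The arrays fell into 2 sets by their median value, which were balanced between the genotypes within each diet but not between the diets. The higher set held 4 normal-diet and 2 high-cholesterol arrays, and the lower set 2 and 4. In the higher set (medians of 3.48 to 3.49) were arrays 1 and 2 of both normal-diet groups and array 1 of both high-cholesterol groups, and the 6 others had medians of 3.423 to 3.434. Within the groups, 53 genes differed between the sets by limma, and 7 did when wild-type normal-diet array 3 was left out. Every comparison below is therefore also given with the sets as a block and within each set. By this balance the block can move diet changes, but not the size of a genotype change or of the interaction. Within a set, a group has 1 or 2 arrays. Counts of genes are therefore given within a set only where each group compared has 2, and sizes of change otherwise.

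The array labelled wild-type normal diet 3 stood apart from its group. Its correlation over genes was 0.982 with the nearest array of its own group and 0.993 with Lats2-CKO high-cholesterol array 3, the nearest of all. Other arrays also had their nearest array in another group, but of the same diet, such as wild-type high-cholesterol array 3 (0.995, against 0.986 within its group). The exception was wild-type high-cholesterol array 1, whose nearest was wild-type normal-diet array 3 (0.986). Only for wild-type normal-diet array 3 was the mean correlation higher with its genotype's other diet (0.987) than with its own group (0.981). Hspa5, a chaperone gene, read 10.47 and 10.53 on wild-type normal-diet arrays 1 and 2, 8.98 on array 3, and 8.65 to 9.04 on the 6 high-cholesterol arrays. Abcg5, a sterol transporter gene, read 8.60 and 8.36 on arrays 1 and 2, 10.45 on array 3, and 10.37 to 10.70 on the 6 high-cholesterol arrays. The array was kept in its group as labelled, and each comparison that uses it is also given without it, an alternative that was fixed in advance for every array.

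Lats2 itself was read at 5.15, 5.14 and 5.69 on the wild-type normal-diet arrays and at 5.12, 5.71 and 5.97 on the wild-type high-cholesterol arrays. The Lats2-CKO arrays gave 4.37, 4.76 and 4.79 on normal diet and 4.62, 4.89 and 4.99 on the high-cholesterol diet. All 6 mutant values lay below all 6 wild-type values, so the genotype labels went with the gene on every array. The change was -0.72 ± 0.16 (SE, 6 arrays against 6) over both diets, -0.68 ± 0.23 on normal diet and -0.77 ± 0.23 on the high-cholesterol diet, yet none passed the threshold over all genes (limma adjusted p = 0.486 over both diets). It was -0.54 within the higher array set and -0.90 within the lower set, and the block leaves -0.72 unmoved by design. The sources used here do not place the probe set against the deleted part of the gene, so the remaining signal is no measure of how complete the loss was. The related kinase Lats1 and their target Yap1 changed by -0.04 ± 0.07 and 0.19 ± 0.14 over both diets, with limma adjusted p of 0.971 and 0.904.

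**Figure D1:**
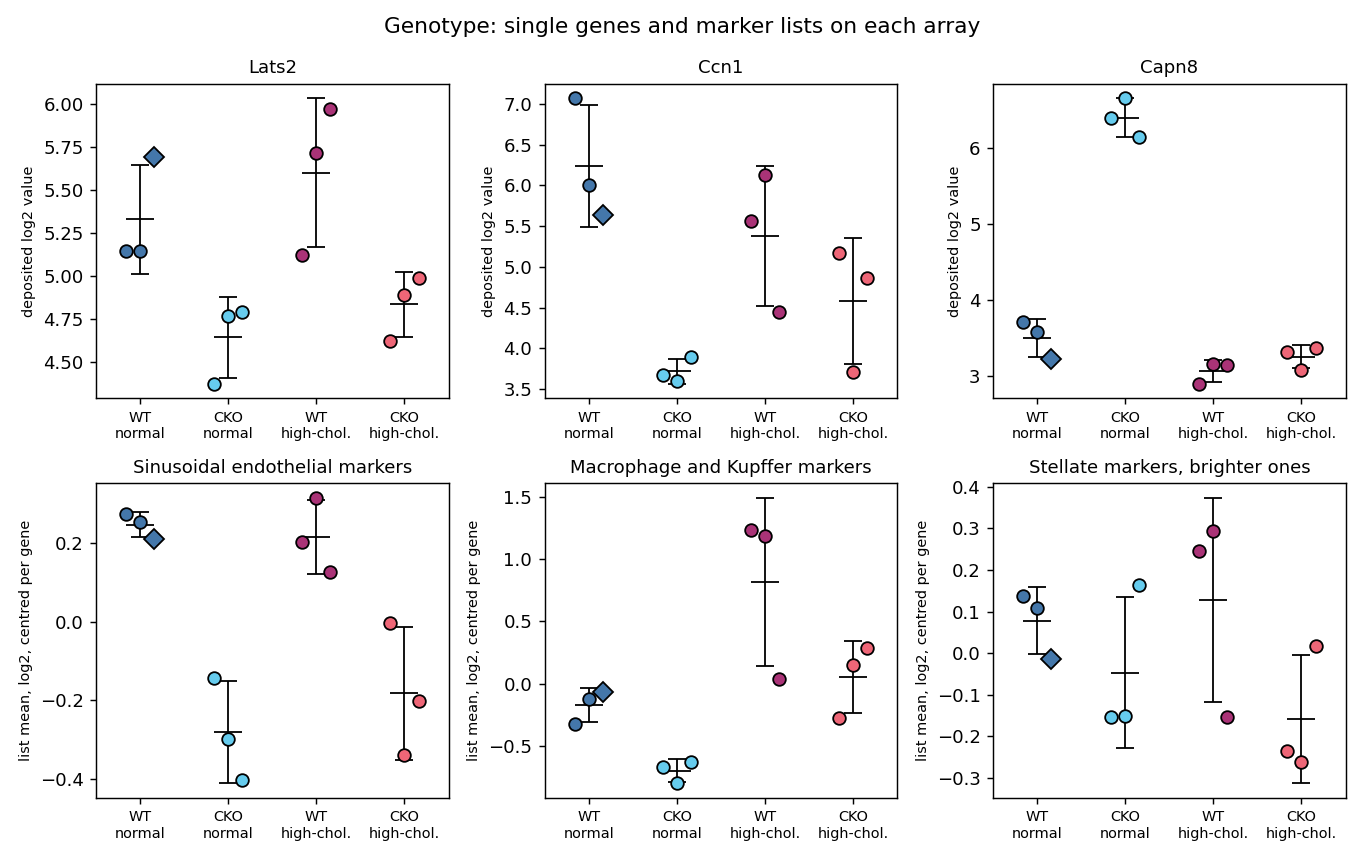
Upper panels: deposited log2 values of Lats2, Ccn1 and Capn8 on each array by group; lower panels: the mean of marker lists on each array, centred per gene (log2). Bars are mean ± SD (n = 3), the diamond is wild-type normal-diet array 3, and Capn8 lay at 6.14 to 6.66 on the Lats2-CKO normal-diet arrays and at 2.90 to 3.71 on the 9 others.

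In wild-type mice the high-cholesterol diet went with lower expression of cholesterol synthesis genes and of chaperone genes, and with higher expression of macrophage markers and sterol export genes. The 19 measured cholesterol synthesis genes, which the sterol sensor SREBP2 drives, all had lower fitted values, with a median of -0.83 and a camera adjusted p of 4.29e-08 in limma. The call came from the preset correlation and was lost at adjusted p = 0.397 with an estimated correlation. Among them Cyp51, which demethylates lanosterol, changed by -1.63 ± 0.44 and Sqle, a rate-limiting enzyme of the pathway, by -3.00 ± 1.02 (SE, 3 arrays against 3). The 23 macrophage and Kupffer cell markers all had higher fitted values, with a median of 0.90 and a camera adjusted p of 2.98e-14 in limma, lost at adjusted p = 0.371 with an estimated correlation. Their centred list mean was 1.23 and 1.18 on wild-type high-cholesterol arrays 1 and 2 but 0.04 on array 3, against -0.32, -0.13 and -0.07 on normal diet. The Kupffer cell lectin Clec4f changed by 0.61 ± 0.13. Of single genes, 0 passed the threshold over all genes in either list, while 8 of the cholesterol synthesis genes and 11 of the macrophage markers passed when adjusted over the list alone.

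Of the 42 lists, 12 passed in wild-type mice, 7 higher and 5 lower, and the estimated correlation left 0 of them, with adjusted p of 0.371 to 0.45 over the 12. Heat shock genes and chaperones (12 of 12 members with lower fitted values, median -0.67) included the co-chaperone Bag3 at -1.63 ± 0.41. Genes of ER stress and the unfolded protein response (18 of 22 lower, median -0.64) included Hspa5, the main chaperone of the endoplasmic reticulum, at -1.17 ± 0.33. Lower medians were also found for pericentral hepatocyte genes (-0.67, 15 of 16 members lower) and for PPAR alpha targets and fatty acid oxidation (-0.31, 20 of 24), where the pantetheinase Vnn1 changed by -1.27 ± 0.23. Higher medians were found for LXR targets and sterol export (0.68, 11 of 13 members), with the phospholipid transfer protein Pltp at 1.17 ± 0.28, for MHC class II genes (0.78, 8 of 8) and for B cell markers (0.52, 11 of 12). Chemokines (0.21, 20 of 27), lysosome and autophagy genes (0.16, 16 of 20) and fibrosis and matrix genes (0.15, 16 of 23) had smaller higher medians. No member of these 10 lists passed over all genes. Adjusted over the list alone, 9 ER stress genes were lower and 1 higher, 5 PPAR alpha targets, 3 heat shock genes and 3 pericentral genes were lower, 3 sterol export genes and 2 chemokines were higher, and the other 4 lists had 0. The B cell median was 0.08 without wild-type high-cholesterol array 2 and 0.82 without array 3. Without array 2 the B cell list was no longer called. Without wild-type high-cholesterol array 1 the fibrosis, MHC class II and lysosome lists were no longer called, the first 2 at medians of 0.0013 and 0.35. Chemokines ranged from 0.12 to 0.51 over the alternatives.

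No single gene passed the threshold for diet in wild-type mice with all 12 arrays. By limma, 0 of 22180 genes passed at a smallest adjusted p of 0.205, while 2349 had an unadjusted p below 0.05, against 1109 by chance, and other settings called 0 to 13 genes when all arrays were kept. The same fit called 67 genes, 65 higher and 2 lower, without wild-type high-cholesterol array 3. Without wild-type normal-diet array 3 it called 516 genes, 175 higher and 341 lower, and 3833 had an unadjusted p below 0.05. The genes with the smallest unadjusted p over all arrays were Ifi204 (1.41 ± 0.18), Ptprj (0.63 ± 0.11), Pla2g7 (1.58 ± 0.30), Atp1b3 (0.59 ± 0.12) and Prps2 (0.67 ± 0.14) on the higher side, with limma adjusted p of 0.205 to 0.307. On the lower side they were Tfg (-0.82 ± 0.13), Eapp (-0.68 ± 0.12), Mlec (-1.29 ± 0.23), Vnn1 and Cdc34 (-0.84 ± 0.15), with adjusted p of 0.301 to 0.307.

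When array 3 was left out, Cyp8b1, Cyp7a1 and Sqle were among the genes that fell in wild-type mice. Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, had changed by -3.74 ± 1.45 with all arrays and fell by 5.98 without array 3. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from -2.25 ± 1.54 to -4.47 ± 0.88 (limma adjusted p = 0.645 and 0.0328), and Sqle to -4.65 ± 0.26 (limma adjusted p = 7.16e-05). Sqle read 2.81 to 2.88 on the wild-type high-cholesterol arrays, below the 30th percentile of all values (3.05), so the size of its fall is uncertain. The ER-associated genes Derl3 and Sdf2l1 were also among the falls with the largest fitted values. The bile acid list as a whole did not pass, with a median of -0.01 over 22 genes (camera adjusted p = 0.994 in limma) and 0.06 without array 3 (camera adjusted p = 0.955). The 5 largest rises were those of Serpina1d, Cyp2b9, Igsf23, Dsg1c and Clec2h. Serpina1d and Cyp2b9 belong to families of near-identical genes whose signals the array may not separate, so both are uncertain. Members past the threshold over all genes then numbered 7 of 19 for cholesterol synthesis (13 adjusted over the list alone), 9 of 22 for ER stress (15), 7 of 16 for pericentral genes (10) and 1 of 12 for heat shock genes (7). In the sterol export list 3 members were higher and 1, Cyp7a1, lower. The macrophage list had 0 of 23 past over all genes and 3 adjusted over the list alone.

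**Figure D2:**
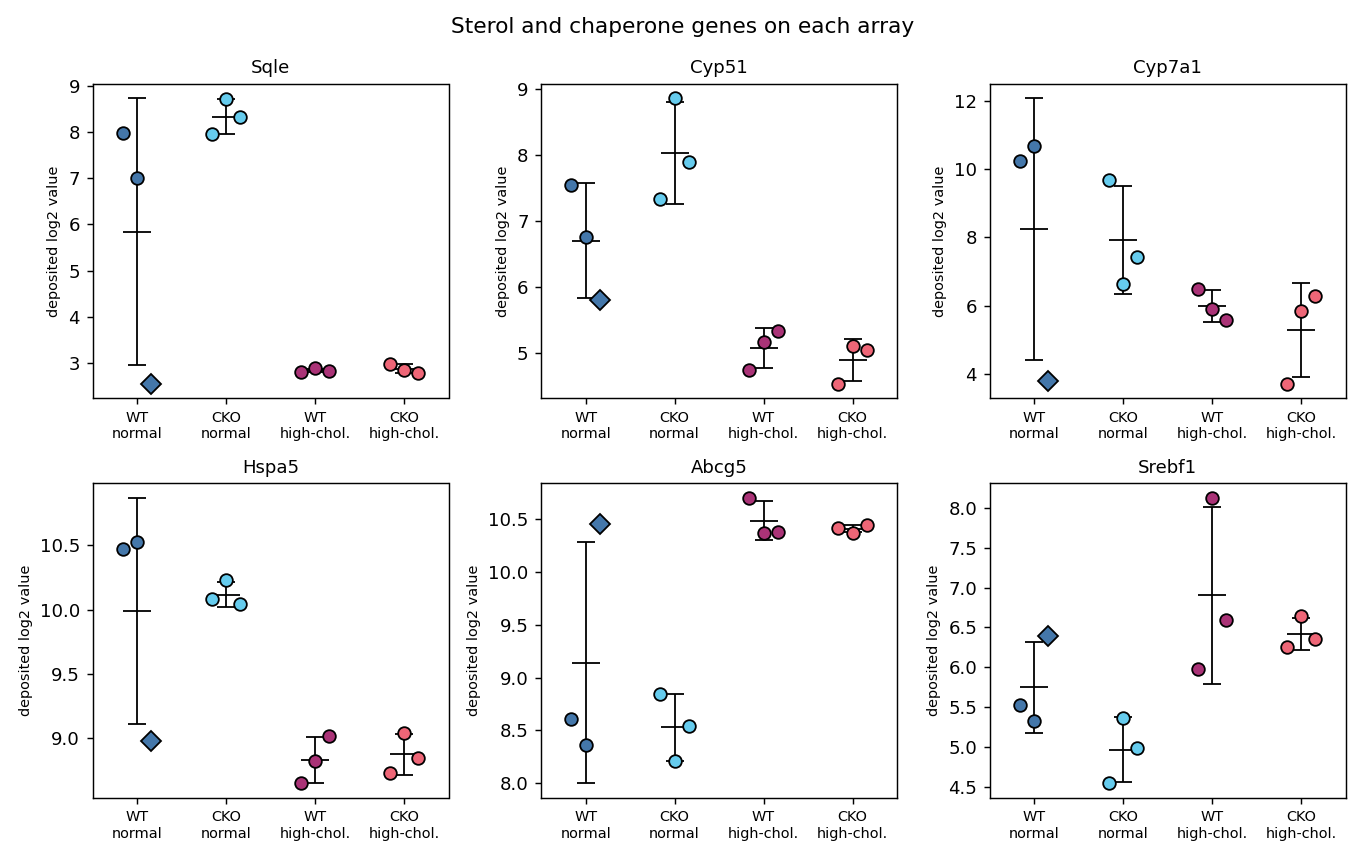
Deposited log2 values of 6 sterol and chaperone genes on each array, by group, with mean ± SD (n = 3); the diamond is wild-type normal-diet array 3. On that array Sqle (2.55), Hspa5 (8.98) and Abcg5 (10.45) lay near the high-cholesterol arrays and away from the other 2 arrays of its group.

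Within each array set the diet contrast rests on a lone wild-type array on 1 side. In the higher set this is high-cholesterol array 1, and in the lower set normal-diet array 3. With the sets as a block, 0 genes passed, and 374 did with the block and without array 3. The median of the cholesterol synthesis list was -1.39 in the higher set, 0.02 in the lower set and -0.74 with the block. That of the macrophage markers was 1.22, 0.86 and 0.87. Of the 12 lists called, 5 kept their sign in both sets and 7 had the other sign in the lower set: cholesterol synthesis, ER stress, pericentral, sterol export, MHC class II, lysosome and fibrosis genes.

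In Lats2-CKO mice 60 genes changed with the diet by limma, 28 higher and 32 lower, with the sterol enzyme gene Cyp51 and the lipid droplet gene Cidec among those that fell. Moxd1, a monooxygenase-like gene of the endoplasmic reticulum, fell by 5.78, Cidec, a lipid droplet protein, by 3.65 and Cyp51 by 3.15 (SE 0.90, 0.53 and 0.44, 3 arrays against 3). The calpain Capn8 changed by -3.14 ± 0.16 and Tlcd2 by -2.15 ± 0.32. Capn8 fell to a dim level (2.90 to 3.71 outside the Lats2-CKO normal-diet arrays), which leaves the size of its fall uncertain. The largest rises were those of the sulfotransferase Sult1c2 (2.51 ± 0.41), the prostaglandin D synthase Ptgds (2.32 ± 0.40), Ddah1, which degrades asymmetric dimethylarginine (2.14 ± 0.26), Ly86, a partner of a toll-like receptor homologue (2.10 ± 0.32), and Coq8a, of coenzyme Q synthesis (1.72 ± 0.26). The limma adjusted p of these 10 genes ran from 1.58e-05 (Capn8) to 0.0475 (Ptgds), and 46 of the 60 changes were at least 2-fold.

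Cholesterol synthesis genes again had a low list median in Lats2-CKO mice, -1.10 over 19 genes, 18 of them with lower fitted values. Pericentral genes had -1.09, and within the lower array set -1.37 against -1.02 for cholesterol synthesis. Of its members 2, Cyp51 and Dhcr7 (-1.50 ± 0.25), fell over all genes, and adjusted over the list alone 11 were lower and 1 higher (camera adjusted p = 3.67e-10 in limma). The call was lost at adjusted p = 0.306 with an estimated correlation. ER stress genes had a median of -0.91 (13 lower and 1 higher adjusted over the list alone, 0 over all genes), where the chaperone Hsp90b1 read -1.32 ± 0.26. Macrophage markers had a median of 0.64 (21 of 23 with higher fitted values, 9 adjusted over the list alone, 0 over all genes), with the tetraspanin Cd9 at 0.64 ± 0.14. Periportal hepatocyte genes had a median of 0.47, and 1 of the 13, the histidine ammonia-lyase Hal, rose by 1.46 ± 0.21 over all genes, against 5 adjusted over the list alone. These 3 lists, too, had adjusted p = 0.306 with an estimated correlation.

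Of the 42 lists, 17 passed in Lats2-CKO mice, 11 higher and 6 lower, and the estimated correlation left 0 of them, with adjusted p of 0.306 to 0.519 over the 17. Cytochrome P450 genes of drug metabolism had the highest median, 1.37, with 14 of 18 members higher and, adjusted over the list alone, 8 higher and 4 lower. Within the lower array set MHC class II genes lay above them, at 1.35 against 1.25. Sterol export genes had a median of 0.63 (6 of 13 adjusted over the list alone), with the sterol transporter Abcg5 at 1.88 ± 0.42, and lysosome genes 0.23 (2 of 20), with Gabarapl1 at 0.80 ± 0.21. Pericentral genes had a median of -1.09 (5 of 16 lower and 1 higher adjusted over the list alone) and heat shock genes -0.57 (6 of 12, 1 of them over all genes). The other 8 were MHC class II (0.95), gluconeogenesis (0.40), chemokine (0.30), cholangiocyte (0.28), NRF2 (0.13) and p53 target genes (0.11) on the higher side, and male-biased (-0.38) and adipose genes (-0.25) on the lower side. In the adipose list, written as a check for contamination by adipose tissue, 1 of 7 members, the lipid droplet gene Cidec, passed over all genes. Of these 7, 3 are also in another list and 4 had a mean above the 30th percentile. In the male-biased list 1 of 18 passed over all genes. The mean of the p53 targets was 0.07. The p53 list was called in 11 of 25 alternatives, male-biased genes in 16 of 25, adipose genes in 17 of 24 and gluconeogenesis in 19 of 25. Without Lats2-CKO high-cholesterol array 2 the NRF2, chemokine and MHC class II lists were no longer called, at medians of -0.052, 0.058 and 0.49.

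Leaving out wild-type normal-diet array 3, which enters this contrast only through the shared spread, gave 222 genes higher and 246 lower in Lats2-CKO mice, and all 60 were among them. The count was 93, 26 and 9 without Lats2-CKO normal-diet arrays 1, 2 and 3, and 5, 10 and 5 without Lats2-CKO high-cholesterol arrays 1, 2 and 3. It was 93, 31 and 33 without wild-type high-cholesterol arrays 1, 2 and 3. With the array sets as a block 33 genes passed. Within each set 1 of the groups has a lone array, so only sizes of change are given there. The cholesterol synthesis median was -1.10 with the block, -1.29 in the higher set and -1.02 in the lower set, and the macrophage median 0.59, 0.39 and 0.80. Of the 17 lists 15 kept their sign in both sets, and p53 targets and NRF2 genes had the other sign in the higher set.

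**Figure D3:**
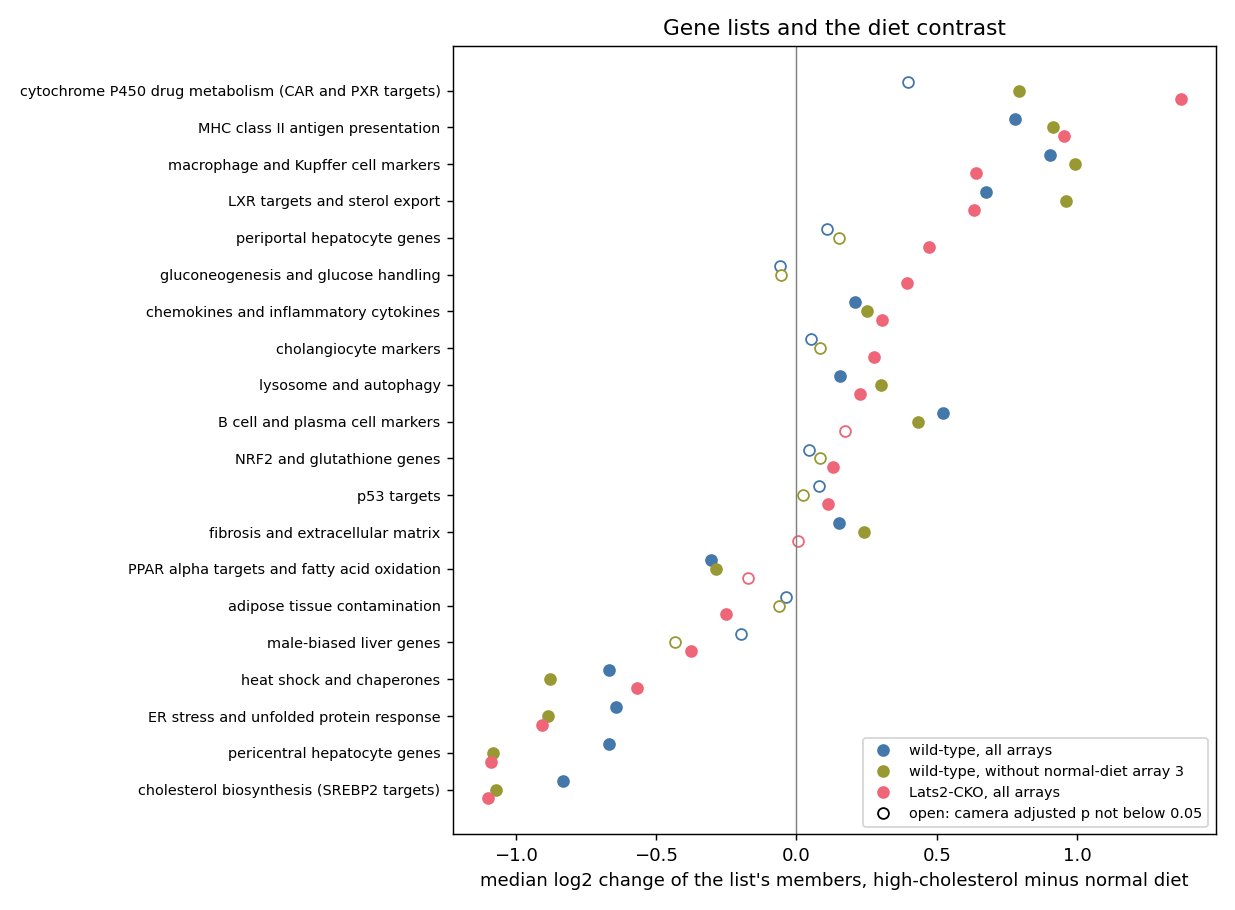
Median log2 change of each gene list, high-cholesterol minus normal diet, for the lists that passed camera in either genotype, in wild-type mice with and without normal-diet array 3 and in Lats2-CKO mice; open circles did not pass. Cholesterol synthesis had the lowest median in both genotypes (-0.83 and -1.10 with all arrays), and macrophage markers were higher in both (0.90 and 0.64).

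The diet responses of the genotypes were compared across genes, which are not independent replicates. The contrasts share no arrays, and their log2 changes correlated at r = 0.507 over all genes, or 0.568 without wild-type normal-diet array 3. The correlation was 0.465 with the array sets as a block. When array 3 was left out, 165 genes were called in both genotypes, 163 in the same direction, where 5.53 would be expected of independent lists. Both contrasts used the same estimate of spread for each gene, so the lists are not independent and 5.53 may be too low. Among the 819 genes called in either, 749 had the same sign in both. With all arrays no overlap could be counted, since limma called 0 genes in wild-type mice. Srebf2 and Srebf1, which encode the regulators of sterol and fatty acid synthesis, read -1.05 ± 0.36 and 1.16 ± 0.47 in wild-type and -1.08 ± 0.36 and 1.46 ± 0.47 in Lats2-CKO mice, and none of these passed (limma adjusted p of 0.199 to 0.43). The sterol exporter Abca1 (0.22 ± 0.12 and -0.20 ± 0.12) and the collagen Col1a1 (0.50 ± 0.18 and 0.22 ± 0.18) did not pass either.

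On normal diet, Lats2-CKO livers had higher Capn8 and Zfand4 than wild-type livers and lower expression of sinusoidal endothelial markers. Capn8, a calpain known from the stomach, rose by 2.89 ± 0.16 (limma adjusted p = 3.84e-05), from a dim level (3.23 to 3.71 on the wild-type arrays) that leaves the size uncertain, and the zinc finger gene Zfand4 by 1.56 ± 0.14 (2.95-fold, adjusted p = 0.0025). The 16 markers of liver sinusoidal endothelial cells had a median of -0.56, with 15 fitted values below 0 and a camera adjusted p of 8.08e-12 in limma. Over all genes 0 of the 16 passed, and 12 were lower adjusted over the list alone, while the call was lost at adjusted p = 0.176 with an estimated correlation. Bmp2, a growth factor made by these cells, read -0.62 ± 0.13 (limma adjusted p = 0.202).

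By limma 3 genes passed for genotype on normal diet, and the third, E030018B13Rik (3.10 ± 0.29, adjusted p = 0.0025), was named only after its values were seen; the other 9 arrays read 2.95 to 3.76, a dim level that leaves the size uncertain. Leaving out wild-type normal-diet array 3 gave 4, the same 3 and Cyp2b9 (3.94 ± 0.29, limma adjusted p = 0.000858), also named after its values were seen; with all arrays it read 1.90 ± 1.25 (adjusted p = 0.731). The count was 17 and 7 without Lats2-CKO normal-diet arrays 1 and 2, and 8 without wild-type high-cholesterol array 1. The next genes by unadjusted p were Ces4a (0.72 ± 0.10), Scara5 (2.55 ± 0.36) and Usp14 (0.64 ± 0.10) on the higher side and Arid1a (-0.86 ± 0.13), Mfsd11 (-0.83 ± 0.13), Klb (-0.92 ± 0.14), Ddah1 (-1.69 ± 0.26) and Atoh8 (-1.13 ± 0.18) on the lower side. Their limma adjusted p ran from 0.0762 to 0.108. Ccn1, a matrix protein gene and a known target of YAP, read -2.52 ± 0.49 (limma adjusted p = 0.154).

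Of the 42 lists, 10 passed for genotype on normal diet, 3 higher and 7 lower, and 0 held with an estimated correlation, at adjusted p of 0.176 to 0.749 over the 10. Over all genes 0 of their members passed. Macrophage markers had a median of -0.46 (21 of 23 lower, 0 adjusted over the list alone), with Cd9 at -0.46 ± 0.14. Acute phase and STAT3 target genes had a median of 0.27 (19 of 23 higher), with the metalloreductase Steap4 among them (limma adjusted p = 0.264). Gluconeogenesis (-0.27), sterol export (-0.42), periportal (-0.20), oxidative phosphorylation (-0.13) and lysosome genes (-0.12) had lower medians (1 periportal gene passed adjusted over the list alone), with the insulin signalling gene Irs1 at -1.01 ± 0.30 and the protease Ctsb at -0.34 ± 0.11. The 7 adipose genes, the list written as a check for contamination, had a median of 0.35 (2 adjusted over the list alone), with Cidec at 1.65 ± 0.53. Whether adipose tissue in the samples made this change was not tested. Cholesterol synthesis genes had a median of 0.30 with all arrays and -0.02 without wild-type normal-diet array 3, where the list no longer passed (camera adjusted p = 0.683 in limma). In all 6 lists passed without that array, 4 of them among these 10 and in the same direction, and 17 passed without wild-type normal-diet array 1. Quantile normalisation split its calls into 4 higher and 5 lower. Sterol export was called in 15 of 25 alternatives, lysosome and periportal genes in 18 of 25, cholesterol synthesis in 19 of 25, and acute phase, gluconeogenesis and oxidative phosphorylation genes in 20 of 25. Without wild-type normal-diet array 3 the acute phase, sterol export, periportal and lysosome medians were 0.089, -0.26, -0.071 and -0.039, and that of cholesterol synthesis was 0.73 without array 1.

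With the array sets as a block, genotype on normal diet changed 11 genes by limma, and within the higher set 3. In the lower set, 1 Lats2-CKO array stands against wild-type array 3, so no count of genes is given. Capn8 read 2.88 and 2.91 within the higher and lower set, and Zfand4 1.37 and 1.94. The endothelial median was -0.52, -0.60 and -0.56, and that of the macrophage markers -0.50, -0.37 and -0.46. All 10 lists kept their sign in both sets.

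On the high-cholesterol diet, Lats2-CKO livers again had lower endothelial and macrophage marker lists than wild-type livers, while no single gene passed. The endothelial markers had a median of -0.47 (15 of 16 lower, 6 adjusted over the list alone, 0 over all genes) and a camera adjusted p of 2.85e-14 in limma. The call was lost at adjusted p = 0.103 with an estimated correlation. The mannose receptor Mrc1 read -0.73 ± 0.16 (3 arrays against 3, limma adjusted p = 1). The macrophage markers had a median of -0.71 (22 of 23 lower, 0 adjusted over the list alone), with a camera adjusted p of 5.46e-13 that became adjusted p = 0.557 with an estimated correlation. Wild-type high-cholesterol arrays 1 and 2 carried this change: the centred list mean was 1.23 and 1.18 there, 0.04 on array 3, and -0.27, 0.15 and 0.29 on the Lats2-CKO arrays. The median was -0.47 without wild-type high-cholesterol array 1 and -1.10 without array 3. Their receptor gene Csf1r read -1.17 ± 0.42.

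By limma, 0 genes passed for genotype on the high-cholesterol diet, and 650 had an unadjusted p below 0.05, against 1109 by chance. Without wild-type high-cholesterol array 3, 22 genes passed, and 1 did without wild-type normal-diet array 1. The smallest unadjusted p belonged to Prelid2 (2.63 ± 0.50), Tnfrsf10b (0.82 ± 0.16), Anxa13 (0.90 ± 0.17), Zfp750 (0.71 ± 0.19) and Nudt18 (0.89 ± 0.25) on the higher side. On the lower side they were Gpr137b (-1.43 ± 0.28), Anxa3 (-1.04 ± 0.22), Mrc1, Zbtb4 (-0.74 ± 0.17) and the water channel Aqp1 (-0.80 ± 0.19), and the limma adjusted p was 1 for all 10.

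Of the 42 lists, 12 passed on the high-cholesterol diet, 3 higher and 9 lower, and 0 held with an estimated correlation, at adjusted p of 0.103 to 0.68 over the 12. None of their members passed over all genes, and outside the endothelial list 1 did adjusted over the list alone, in the sterol export list. B cell markers had a median of -0.49 (10 of 12 lower), with Bank1 at -1.13 ± 0.43, and sterol export genes -0.31 (11 of 13), with Pltp at -1.16 ± 0.28. Stellate cell markers had a median of -0.19 (16 of 16), with Vim at -0.64 ± 0.33, and fibrosis genes -0.14 (17 of 23). Vim read -1.61 within the higher array set and -0.15 within the lower. Clock genes (-0.21, 13 of 18), chemokines (-0.16, 21 of 27) and lysosome genes (-0.12, 16 of 20) were the other lower lists. Type I interferon genes had a median of 0.28 (20 of 22 higher), with Mx2 at 1.22 ± 0.42, fatty acid synthesis genes 0.10 (18 of 19) and proliferation genes 0.06 (24 of 31). Several of these lists hung on single arrays. Clock genes were called in 12 of 25 alternatives, with a median of 0.027 without wild-type high-cholesterol array 2, and chemokines in 18 of 25 (-0.34 to -0.017). B cell markers were at -0.024 and no longer called without wild-type high-cholesterol array 2, and fibrosis and fatty acid synthesis genes at -0.018 and 0.015 without array 1. Sterol export was at -0.078 without Lats2-CKO high-cholesterol array 1 and interferon genes at -0.11 without array 2, both no longer called.

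With the array sets as a block 0 genes passed for genotype on the high-cholesterol diet by limma, and within the lower set 0 did. In the higher set 1 array stands against 1, so no count of genes is given. The endothelial median was -0.30 and -0.57 within the higher and lower set, and the macrophage median -1.42 and -0.35. The block leaves the medians over all arrays, -0.47 and -0.71, unmoved by design. Of the 12 lists 9 kept their sign in both sets. Interferon genes had medians of -0.26 and 0.42, and a median of -0.11 without Lats2-CKO high-cholesterol array 2, where the list no longer passed. Fatty acid synthesis genes and chemokines also had the other sign in 1 set.

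Averaged over both diets, the endothelial markers were 1 of 12 lists that passed between the genotypes. All 16 had lower fitted values in Lats2-CKO livers, with a median of -0.43, and 12 passed adjusted over the list alone (0 over all genes). The list passed camera at the preset correlation (adjusted p = 1.87e-21 in limma), held at adjusted p = 0.0296 with an estimated correlation, and passed fry (adjusted p = 0.00575). It was the only 1 of the 12 lists called here to hold with an estimated correlation. When wild-type normal-diet array 3 was left out it had adjusted p = 0.077 with an estimated correlation. Its mean on each array was lower on all 3 Lats2-CKO arrays than on all 3 wild-type arrays of the same diet, for both diets. Oit3, a secreted protein of these cells, read -0.73 ± 0.14 (6 arrays against 6, limma adjusted p = 0.427). The median was -0.39 within the higher array set and -0.55 within the lower set, and the block leaves -0.43 unmoved by design.

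The 23 macrophage markers all had lower fitted values in Lats2-CKO livers over both diets, with a median of -0.65 and 4 past the threshold adjusted over the list alone (0 over all genes). The camera adjusted p of 2.44e-13 in limma became adjusted p = 0.351 with an estimated correlation. Lysozyme, Lyz2, read -0.99 ± 0.24. The other 10 lists called were lost at adjusted p of 0.351 to 0.704 with an estimated correlation, and 0 of their members passed over all genes. Sterol export (-0.34, 3 lower adjusted over the list alone, Pltp -0.90 ± 0.20), B cell (-0.30), lysosome (-0.14, Ctsb -0.26 ± 0.08), gluconeogenesis (-0.13) and oxidative phosphorylation genes (-0.10) had lower medians. Adipose (0.24, Lipe 0.24 ± 0.08), interferon (0.17), acute phase (0.16, Steap4 1.11 ± 0.38), cholesterol synthesis (0.16) and complement genes (0.07) had higher ones. Leaving out wild-type normal-diet array 3, the median of cholesterol synthesis genes was 0.01, and 8 of the 12 lists were still called in the same direction. Of the 12, 10 kept their sign in both array sets, and acute phase and interferon genes had the other sign in the higher set. Complement genes were called in 9 of 24 alternatives, gluconeogenesis in 14, cholesterol synthesis in 16, oxidative phosphorylation in 17, interferon and B cell lists in 18 and acute phase genes in 19. The B cell median was -0.10 without wild-type high-cholesterol array 2, the interferon median 0.0033 without Lats2-CKO high-cholesterol array 2, and sterol export -0.15 without wild-type normal-diet array 3.

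For single genes over both diets, Capn8 alone passed by limma (1.54 ± 0.11, adjusted p = 0.000755), and it was named here after its values were seen because its diets differed. Without wild-type normal-diet array 3 Cyp2b9 passed too (2.19 ± 0.19, adjusted p = 0.00503), and without wild-type high-cholesterol array 3 there were 8 genes. Without wild-type normal-diet array 1, Lats2-CKO normal-diet array 1 or Lats2-CKO normal-diet array 3 there were 3. With the array sets as a block 2 passed. Within each set 1 of the diets has a lone array per genotype, so no count of genes is given there. Zfand4 (0.75 ± 0.10), Scara5 (1.55 ± 0.26), Moxd1 (2.96 ± 0.63), B3galt1 (1.42 ± 0.32) and the chemokine Cxcl1 (1.73 ± 0.41) followed on the higher side. On the lower side were Cyp4b1 (-1.27 ± 0.21), Sema6a (-0.66 ± 0.11), Aqp1 (-0.77 ± 0.13), Oit3 and Zbtb4 (-0.62 ± 0.12), and the limma adjusted p of the 10 ran from 0.0928 to 0.565. The YAP targets Ccn1 and Ccn2 read -1.66 ± 0.34 and -0.79 ± 0.27 (adjusted p = 0.46 and 0.759). The p53 targets Cdkn1a (0.11 ± 0.57) and Mdm2 (-0.03 ± 0.09), Srebf1 (-0.63 ± 0.33), Srebf2 (0.19 ± 0.25), Sqle (1.26 ± 0.72), Cyp7a1 (-0.52 ± 1.09), Abca1 (0.04 ± 0.09), Col1a1 (-0.09 ± 0.13) and Afp (0.14 ± 0.09) had adjusted p of 0.848 to 0.988.

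The interaction asked whether the diet acted differently on the genotypes. Capn8 was the 1 gene that passed (-2.70 ± 0.23, limma adjusted p = 0.00293): it fell by 3.14 with the diet in Lats2-CKO mice and read -0.44 in wild-type mice. Outside the Lats2-CKO normal-diet arrays it read 2.90 to 3.71, a dim level that leaves these sizes uncertain. Zfand4 came next at -1.62 ± 0.20 (adjusted p = 0.072). Spon2 (1.76 ± 0.32), Tfcp2l1 (1.59 ± 0.31), Gabbr2 (1.29 ± 0.26), Wdtc1 (1.25 ± 0.22), Klb (1.03 ± 0.20), Taf2 (-1.19 ± 0.23), Fam3c (-0.79 ± 0.15) and Usp14 (-0.78 ± 0.14) followed, each at a limma adjusted p of 0.602. Of the 42 lists 0 passed camera in limma, and the smallest p in their lists belonged to the thioesterase Acot2 (1.86 ± 0.49), Hal (1.13 ± 0.30), Cyp2c29 (0.76 ± 0.25), Ngfr (-0.37 ± 0.16), Irs1 (0.93 ± 0.42) and the desaturase Scd1 (0.68 ± 0.33). Without wild-type normal-diet array 3 Cyp2b9 also passed, at -3.49 ± 0.39 (adjusted p = 0.0421), which made 2 genes; there were 2 also without wild-type normal-diet array 1, Lats2-CKO normal-diet array 1 or 3, or wild-type high-cholesterol array 3. Up to 8 lists passed when single arrays were left out (8 without wild-type normal-diet array 1). Some lists also passed with a trended and robust prior, with array weights, or with the replicate number as a block. With the array sets as a block 2 genes passed, and no count is given within the sets, where groups have lone arrays. Capn8 read -2.47 and -2.83 within the higher and lower set, and the block leaves -2.70 unmoved by design.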

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

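The tests of the diet position of wild-type normal-diet array 3, of the array sets on that array, of the share of non-hepatocyte cells and all 3 tests on Capn8 and its companions were chosen only after the result was seen.

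Capn8 responded to genotype differently on the 2 diets, by a test of the difference itself (-2.70 ± 0.23, limma adjusted p = 0.00293). With Zfand4 and E030018B13Rik, the last chosen after its values were seen, it was higher on the 3 Lats2-CKO normal-diet arrays than on the 9 others. Zfand4 read 6.56 to 6.99 against 4.83 to 5.33 and E030018B13Rik up to 7.24 against 2.95 to 3.76. Stomach RNA would bring its abundant transcripts, but 12 gastric markers had a median change of 0.0535 and none exceeded 3.35 on these arrays. The array sets were balanced between the genotypes on normal diet, so a difference between them cannot by itself make the genotype change. Within groups the sets differed by at most 0.137 of that change in the 3 genes. This adds little, since genes called here vary little within groups. A variant of the line stays open: the median change on the high-cholesterol diet was 0.0292, but the genes were picked as high on 3 arrays alone, and a variant may act with the diet. A shared cage or litter was not tested, so a genotype effect that depends on the diet may explain the pattern only as a hypothesis.

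The array labelled wild-type normal diet 3 lay with the high-cholesterol arrays. On a diet axis made of 265 genes from the Lats2-CKO arrays alone (0 for normal diet, 1 for high-cholesterol diet) it lay at 0.973, while wild-type normal-diet arrays 1 and 2 lay at 0.179 and 0.267 and the wild-type high-cholesterol arrays at 0.964 to 0.978. The array sets are argued against, since the Lats2-CKO normal-diet array of the same set lay at 0.262 on an axis made from the other wild-type arrays. Withdrawn food stays open, because PPAR alpha targets differed from arrays 1 and 2 by a median of 0.112, between the bounds set for it, though sterol export genes at 0.864 (10 of 13 above 0) go against it and bile acid genes were at 0.159. RNA of a mouse fed the high-cholesterol diet may explain the position on the axis. No high-cholesterol array lay out of place as a partner for a swap (Lats2-CKO arrays 0.907 to 0.99). But 2 probe sets without a single gene symbol, called for genotype on normal diet also without array 3, go the other way. On them array 3 read 6.31 and 6.35, against 4.33 to 4.71 and 5.35 to 5.90 in wild-type mice on the high-cholesterol diet. On the 7 called for diet in wild-type mice without array 3, it lay 0.545 to 0.828 of the way to the high-cholesterol mean. On each of these 7 it was outside the range of the high-cholesterol arrays of both genotypes, on the normal-diet side. These 7 were picked for a wide gap between the diets on the other wild-type arrays. An array left out of such a pick tends to lie nearer the middle, so this position decides little. On the axis of 239 genes from those wild-type arrays, array 3 lay at 0.962, within the range of the Lats2-CKO high-cholesterol arrays. A single wrong label thus stays possible and was not shown.

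The endothelial markers were lower in Lats2-CKO livers on both diets. The array sets are argued against by a median of -0.388 in the set where the change is smaller, and chance order of the arrays by an exact two-sided permutation test for this list taken alone (p = 0.005, the smallest that 400 regroupings allow), while over the 42 lists tested its exact adjusted p was 0.14, and 0.005 by itself cannot pass there. A smaller share of all non-hepatocyte cells cannot be told apart for the endothelial markers: their mean changed by -0.463 and that of the 9 brighter stellate markers by -0.207, a difference of -0.256 with a 95% interval of -0.533 to 0.021 that holds 0. Macrophage markers (-0.642) moved apart from the stellate ones by -0.436 (-0.8 to -0.0709). This does not exclude an equal loss of cells. All 23 macrophage markers were set against only the 9 brighter stellate ones, and lists can differ in signal over background and in expression by other cells. The macrophage mean also rested on wild-type high-cholesterol arrays 1 and 2 (1.23 and 1.18, against 0.04 on array 3). Cholangiocyte markers (-0.04, -0.183 to 0.103) decide nothing because only 2 of 12 lay above the 75th percentile of all values. A change in the endothelial cells by genotype may also explain the pattern and stays a hypothesis.

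Among 17824 probe sets without a single gene symbol, 3 differed by genotype on normal diet by limma, all lower in Lats2-CKO livers. Their changes were -2.33 ± 0.21, -2.27 ± 0.18 and -1.85 ± 0.21 (adjusted p of 0.00231 to 0.0315). Over both diets 1 differed (-1.21 ± 0.12, limma adjusted p = 0.033). Without wild-type normal-diet array 3, limma called 2 on normal diet, 0 over both diets and 7 for diet in wild-type mice (2 higher, 5 lower; 0 with all arrays). These signals lie outside the genes compared, and the probe sets are not named here. With groups of 3 arrays, single arrays were not tested as outliers.

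For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split gave 0 genes for diet in wild-type mice (10 of 10 splits as many, highest other 3), 60 in Lats2-CKO mice (1 of 10, highest other 0), 3 for genotype on normal diet (2 of 10, highest other 7) and 0 on the high-cholesterol diet (10 of 10, highest other 10). For lists the real and highest other counts were 12 and 18 (3 of 10 splits), 17 and 12 (1 of 10), 10 and 10 (2 of 10) and 12 and 16 (3 of 10). The split that follows the array sets gave 0 genes and 10 lists in wild-type and 0 genes and 7 lists in Lats2-CKO mice. Over both diets 19 of 100 splits gave as many genes as the real 1 (highest other 14) and 24 of 100 as many lists as the real 12 (highest other 20). For the interaction 18 of 100 gave as many genes as the real 1 (highest other 5) and 100 of 100 as many lists as the real 0 (highest other 20). Of these 19 and 18 splits, 12 and 12 kept the normal-diet groups whole and so held the real normal-diet difference, and of the 88 that broke them up 7 and 6 gave as many genes. Chance was thus not excluded for the first 3 of these 4 counts, while a count of 0 is matched by every split. The splits with 14 and 5 genes, several times the real count, both exchange wild-type array 3 and Lats2-CKO array 2 on the high-cholesterol diet, which points to a structure of the arrays whose source was not tested.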

How the results depend on the processing

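The block for the array sets, alone and with wild-type normal-diet array 3 left out as well, was chosen only after the result was seen; the other alternatives were planned.

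Of the values of called lists under the alternatives 1293 kept direction and call, 262 kept direction only and 5 reversed. For called genes 252 kept both and 107 direction only. For genes not called 5249 stayed so, 185 passed and 81 reversed. Many alternatives cannot move a log2 change. These are the other list tests, the prior, no moderation, the fit on only the groups compared and the replicate block. Leaving out an array of a group not compared cannot move it either, nor can the array-set block for genotype. The kept directions are thus partly fixed in advance and do not measure how firm the results are. Capn8 was called on normal diet in all 24 alternatives that gave a value. The endothelial list over both diets was called in all 24 of its alternatives, at adjusted p of 1.48e-25 to 0.0296. Zfand4 on normal diet was called in 22 of 24, at limma adjusted p of 0.00182 to 0.1. The cause of the changes below was not tested, unless fewer arrays or genes made them. Signal over background limits dim genes: 15401 genes lay above 3.05.

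Genes changed by diet in wild-type mice numbered 0 with all arrays, 1 with no moderation of the variance, 13 with array weights, 374 with the array-set block and without array 3 together, and 0 to 516 with single arrays left out (516 without wild-type normal-diet array 3). In Lats2-CKO mice the 60 became 265 with only the groups compared, 98 with a trended and robust prior, 6 with no moderation, 274 with array weights, 109 without dim genes, 9 with every probe set tested, 33 with the array-set block, 573 with both changes, and from 5 to 4.7e+02 with single arrays left out (222 higher and 246 lower without wild-type normal-diet array 3). For genotype on normal diet the 3 became 1 with only the groups compared, 5 with the trended prior, 1 with no moderation, 6 with every probe set, 11 with the array-set block, 6 with both changes and 3 to 17 with single arrays left out. On the high-cholesterol diet the 0 became 0 to 22. Over both diets the 1 became 2 with the trended prior, 3 with array weights, 2 with every probe set, 2 with the array-set block, 2 with both changes and 1 to 8. The 1 interaction gene became 2 with the trended prior, 0 with no moderation, 3 without dim genes, 2 with the array-set block and 1 to 2.

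Of the lists called, the estimated correlation left 0, 0, 0, 0 and 1 for diet in wild-type and Lats2-CKO mice and genotype on normal diet, high-cholesterol diet and both, and fry called 0, 0, 1, 0 and 1. On normal diet 5 passed without dim genes, 3 with both changes and 6 to 17 with single arrays left out; over both diets 7 passed with both changes. For the interaction 6 passed with the trended prior, 2 with array weights, 1 with both changes and 0 to 8 with single arrays left out. The correlation of the diet responses was 0.563 with array weights, 0.413 with every probe set, 0.594 with both changes and 0.420 to 0.568 with single arrays left out.

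The replicate numbers were not taken to pair the arrays: of 18 same-numbered pairs 7 had r over 0.1 (0.00237 to 0.176, all above 0), and 9 of 12 arrays correlated best with an array of their own number. This is a hint from the data, not the design, and the array sets share it, since the arrays numbered 1 are all in the higher set and those numbered 3 all in the lower. With the replicate number as a block, 58 genes changed by diet in Lats2-CKO mice and 5 interaction lists passed.

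Interferon genes by genotype on the high-cholesterol diet ranged from -0.11 (without Lats2-CKO array 2) to 0.50 with single arrays left out. Clock genes there ranged from -0.32 to 0.027 (without wild-type array 2), NRF2 genes for diet in Lats2-CKO mice from -0.052 (without high-cholesterol array 2) to 0.27, and cholesterol synthesis by genotype on normal diet from -0.016 (without wild-type array 3) to 0.73, and it was -0.069 with both changes. With quantile normalisation Afp read 0.0034 for diet in wild-type mice and -0.0081 for genotype on the high-cholesterol diet, and Mdm2 0.016, 0.023 and 0.019 for genotype on normal diet, high-cholesterol diet and both. Median centring gave Afp 0.0030 for diet in wild-type mice. Array weights gave Mdm2 0.061 and Afp -0.0028 on the high-cholesterol diet, Mdm2 0.025 over both diets, and Srebf2 0.14 and Cyp7a1 1.32 for the interaction. The mean of a gene's probe sets gave Yap1 -0.021 on the high-cholesterol diet and Ccn2 0.0075 for the interaction. The array-set block gave Mdm2 -0.0066 for diet in wild-type mice. With both changes Mdm2 read -0.089 and -0.0066 for diet in wild-type and Lats2-CKO mice, Srebf2 -0.33 on normal diet, -0.075 over both diets and 0.50 for the interaction, Cdkn1a -0.063 over both diets, and Cyp7a1 1.93 for the interaction.

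With single arrays left out, the genes that reversed had these ranges of log2 change. For diet in wild-type mice the ranges were Cdkn1a -0.69 to 0.58, Mdm2 -0.025 to 0.10 and Afp -0.055 to 0.015. For diet in Lats2-CKO mice the ranges were Mdm2 -0.051 to 0.18. For genotype on normal diet the ranges were Lats1 -0.052 to 0.14, Srebf2 -0.17 to 0.56, Cdkn1a -1.03 to 0.46, Mdm2 -0.099 to 0.054, Cyp7a1 -2.55 to 0.90 and Col1a1 -0.041 to 0.20. For genotype on high-cholesterol diet the ranges were Yap1 -0.034 to 0.21, Srebf1 -0.94 to 0.13, Srebf2 -0.099 to 0.44, Sqle -0.019 to 0.079, Cdkn1a -0.056 to 1.22, Mdm2 -0.12 to 0.11, Cyp7a1 -1.21 to 0.070 and Afp -0.043 to 0.071. For genotype over both diets the ranges were Lats1 -0.074 to 0.023, Cdkn1a -0.29 to 0.60, Mdm2 -0.079 to 0.035 and Cyp7a1 -1.63 to 0.092. For genotype by diet interaction the ranges were Lats2 -0.32 to 0.10, Yap1 -0.33 to 0.064, Srebf1 -0.16 to 0.91, Srebf2 -0.39 to 0.35, Mdm2 -0.084 to 0.15, Ccn2 -0.57 to 0.21 and Cyp7a1 -1.61 to 1.83.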

Other observations

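The test of YAP/TAZ targets was chosen only after the result was seen, while that of the 2 cell types was set out beforehand.

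Loss of Lats2 may raise targets of YAP and TAZ, which the kinase restrains. The 25 targets had a median change of -0.0203 over both diets, with 12 above 0 and a camera adjusted p of 0.249 in limma. Their mean was also below 0, at -0.134 (exact permutation p = 0.065). It was lower on all 3 Lats2-CKO normal-diet arrays than on all 3 wild-type ones. Ccn1 read -1.66 ± 0.34 and Ccn2 -0.79 ± 0.27, neither past the threshold. No rise of the list was thus seen, and the median lay on the side set against a rise (at or below 0). A median near 0 over members that go both ways, and a mean short of the threshold, leave the hypothesis undecided. Which cells lost the gene is not stated, so a rise in a minor cell type would be hidden.

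Endothelial and macrophage markers were both lower in Lats2-CKO livers, and fewer cells of both types together could cause this. After group means were removed, the 2 list means correlated over 12 arrays at r = 0.0337 (permutation p = 0.926) and rho = -0.168 (permutation p = 0.624), the 1 relation computed. Without the 2 farthest arrays r was 0.332. The arrays are too few to decide.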
